A study of Homo sapiens with 8 samples.

How the data were processed

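MeRIP-seq was carried out on chromatin-associated, ribosome-depleted RNA of HEC-1-A cells, with an m6A spike-in from a commercial enrichment kit added before fragmentation and a strand-preserving total RNA library kit, per the labels' protocols. Control and METTL3 knockdown cells were each profiled in 2 immunoprecipitated libraries, and groups and replicate numbers came from the sample titles. The 4 matching input libraries were not analysed here as samples of their own.

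The reads were handled with CASAVA, Trimmomatic 0.38, HISAT2 2.1.0, SAMtools 1.9 and MACS2 on hg38, per the submitters' processing notes, which give no settings. The deposited files are peak lists without header, one per immunoprecipitated library, and the peak names in them show that peaks were called per library and separately for the 2 strands. Each deposited peak has a fold (the ratio of the read pileup at the summit to a local background), the -log10 of a p-value and the -log10 of a q-value from the caller, and a display score that is a rescaled q. The lowest deposited -log10 q in each list was near 2, which equals a q-value of 0.01. The reference of the authors held alternate contigs and 2 spike-in sequences, as the chromosome names in the deposited files show. Because the lists were called separately, fold, score and q themselves were used only to describe, rank or filter peaks within a list. Across lists, the number and position of peaks were compared, and so was a background derived from fold and p-value, as a measure of depth and, relative to the floor of each library, at shared regions. A deeper library gives more peaks at the same threshold, and per-list calling therefore ties each count to depth.

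Depth was approximated from each peak by inverting the relation of the fold, the p-value and a Poisson background. The recomputed -log10 p matched the deposited one within 0.01 for 99.6% of peaks in control replicate 2 and 99.8% in knockdown replicate 1, but for only 9.92% in control replicate 1 and 8.70% in knockdown replicate 2, where the recovered values are approximate. The background floor, the mean over strands of percentile 10 of the recovered background, was 17.6, 27.4, 16.7 and 17.5 reads in control replicates 1 and 2 and knockdown replicates 1 and 2. In the closely matched libraries no recovered pileup exceeded 750 reads, a value reached by 15 of 92508 peaks.

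Peaks of the 4 lists were merged by strand with no gap into regions, and a region counted as present in a library where at least 1 base overlapped a peak. Summits were assigned to genes of the RefSeq table for GRCh38.p14 by gene span, protein-coding before lncRNA before other genes. The table used gives no strand, so this assignment ignored strand, and peaks called on the strand opposite to a gene count towards its number of peaks. The table used has gene spans only, so the planned priority of exons over introns, the shares by untranslated region, coding sequence and stop codon, and the alternative of exonic summits were not run. The planned share of summits with an m6A motif was not run either, as no genome sequence was used here. Of the summits on the autosomes and chromosome X, 91.2% lay inside a protein-coding or lncRNA gene, against 61.1% after a shift of 1000000 bases. Of the assigned peaks, 5.29% had several genes of equal priority and were given to each.

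Group values were compared by exact permutation of the 4 libraries, two-sided, and counts of group-specific regions and genes were set beside the crossed splits. A gene had more peaks in a group when its lower value in that group exceeded the higher value in the other. Gene lists, 21 in all, were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over lists, and again against 10000 random lists matched on gene length or number of peaks. Genes and regions are not replicates, so those p-values describe these libraries. Shares of regions have 95% Wilson intervals, which cover counting error only. Gene lists, the rule for named genes and all tests other than those said to be added were fixed before the data were examined. The Fisher tests of region classes by presence in the libraries were not among those fixed beforehand and were added. The rule named, in each direction, the 12 genes present in both libraries of one group and neither of the other that ranked highest by the lower of their 2 peak numbers, with ties ordered by the worse of the within-list percentiles of q of the best peak, the 6 regions per direction with the best rank in both lists, the 6 genes with most peaks, up to 4 members per list by control peaks, and METTL3, leaving out chromosome Y and the X-inactivation transcript. Other genes, among them 8 in each direction with the widest gaps and the list members with more peaks in one group, were named after their values were seen. Some genes that these choices cover are not reported here.

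Alternatives were a stricter q, equal list lengths, another overlap, a merging gap of 100 bases, main chromosomes alone, summits in exactly 1 gene, matched random lists, each library left out, and within-number ratios. Strand-blind merging, removal of peaks under a stronger peak of the opposite strand, and the list test for genes with more knockdown peaks were added after seeing the data. The counting steps were tested on simulated data. For 29419 simulated regions, 178 of 200 planted control-specific and 179 of 200 planted knockdown-specific regions were recovered, with 125 and 25 false ones. The simulated regions were those called in all 4 libraries, drawn at each library's rate of detecting regions that the other libraries held. Unequal detection rates alone thus gave more false regions on the control side. Weaker regions, as most group-specific ones were, were not simulated, so their false calls were not measured. The list test called 10 of 10 planted lists and 0 of 90 others. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.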

Results

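The data were peak lists from m6A immunoprecipitation and sequencing (MeRIP-seq) of RNA that stays with chromatin, in HEC-1-A, an established human endometrial adenocarcinoma line. N6-methyladenosine (m6A) is a methyl mark on adenosines of RNA, and METTL3 is the catalytic subunit of the complex that writes it on most polyadenylated transcripts. The comparison asked how the m6A map of chromatin-associated RNA differs between cells with METTL3 knocked down and control cells. There were 2 control and 2 knockdown immunoprecipitated libraries, each with its own list of peaks, and 4 input libraries that were not analysed here as samples of their own. The lists held 42896 peaks in control replicate 1, 50320 in control replicate 2, 42467 in knockdown replicate 1 and 41693 in knockdown replicate 2. Total read numbers were not given in the sources used here. A background floor recovered from the fold and p-value of each peak stood at 1.56 times that of control replicate 1 in control replicate 2, 0.946 times in knockdown replicate 1 and 0.994 times in knockdown replicate 2, so control replicate 2 was the most deeply called list. With 2 libraries against 2, the smallest p-value of an exact two-sided permutation test is 0.333, so no single value compared between the groups could pass 0.05 in that test. The labels do not say whether replicates were separate cultures, so the spread between them may be technical.

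METTL3 itself, on chromosome 14 from 21498138 to 21511340 (hg38), carried 5 peaks in each of the 4 libraries. A number of peaks on a gene does not measure its RNA level, so this value does not check the knockdown. Peaks were frequent on transcripts of the m6A machinery. Of 21 writers, erasers and readers, 19 had peaks in all 4 libraries, with 100 peaks ± 5.66 (SD, n = 2) in control and 102 ± 0 (SD, n = 2) in knockdown over the whole list. ZC3H13, a scaffold protein of the writer complex, held 13 and 16 control peaks and 14 and 15 knockdown peaks. IGF2BP3, an m6A reader that binds messenger RNA, held 11 and 13 against 13 and 12, and VIRMA, another writer component, held 6 and 6 against 6 and 7. ALKBH5, an m6A demethylase, held 3 peaks in each control library and 1 and 2 in the knockdown libraries. The nuclear reader YTHDC1 held 9 and 8 control peaks and 10 in each knockdown library, and IGF2BP2 held 5 and 6 against 7 and 8.

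Knockdown libraries had fewer and narrower peaks on average, with the gap in number resting largely on 1 library. The control lists averaged 46608 ± 5250 peaks (SD, n = 2) and the knockdown lists 42080 ± 547 (SD, n = 2), a ratio of 0.903 (exact permutation p = 0.333, two-sided). Without control replicate 2 the ratio was 0.981. The covered length was 21.7 Mb ± 2.70 (SD, n = 2) in control and 18.5 Mb ± 0.00562 (SD, n = 2) in knockdown, a ratio of 0.849 (exact permutation p = 0.333). The median peak was 311 bases wide in both control libraries and 293 and 297 bases wide in the knockdown libraries. Most summits lay within protein-coding genes, 83.1% ± 0.114 (SD, n = 2) in control and 84.3% ± 0.110 (SD, n = 2) in knockdown. The share of summits outside annotated genes was 9.33% ± 0.0133 (SD, n = 2) in control and 8.51% ± 0.0725 (SD, n = 2) in knockdown, a difference of -0.823 percentage points that exceeded the spread within either group (exact permutation p = 0.333). The share in lncRNA genes was 5.60% ± 0.0590 and 5.30% ± 0.0169 (SD, n = 2 each). With lists of equal length the difference outside genes was -0.473 points. Peaks on alternate or unplaced contigs had no gene in the table used and count as outside genes. They numbered 930 and 1086 in control replicates 1 and 2, and 910 and 883 in knockdown replicates 1 and 2. On chromosomes 1 to 22 and X alone the difference outside genes was -0.823 points.

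When the peaks of the 4 lists were merged by strand into 58293 regions, 29419 (50.5%) were called in all 4 libraries. A further 5007 regions were called in both control libraries and neither knockdown library, and 2037 in both knockdown libraries and neither control library. These 7044 regions that followed the treatment compare with 1449 and 1403 for the crossed splits that mix control with knockdown. Libraries of the same group shared 74.7% ± 0.343 (SD, n = 2 pairs) of their joint regions, and libraries of different groups shared 65.3% ± 1.42 (SD, n = 4 pairs). Of the regions in a control library, 74.7% ± 4.76 (SD, n = 4 pairs) were also called in a knockdown library, against 86.4% ± 11.4 (SD, n = 2 pairs) in the other control library. Of the regions in a knockdown library, 84.2% ± 3.77 (SD, n = 4 pairs) were also called in a control library, against 85.4% ± 1.04 (SD, n = 2 pairs) in the other knockdown library, a gap within the spread between pairs. The excess on the control side shrank from 2.46 times to 1.26 times when each list was limited to its best peaks in the number of the shortest list, which gave 3567 control-specific and 2829 knockdown-specific regions. The crossed splits then gave 1354 and 1363 regions, divided over their sides as 600 against 754 and 629 against 734.

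**Figure D1:**
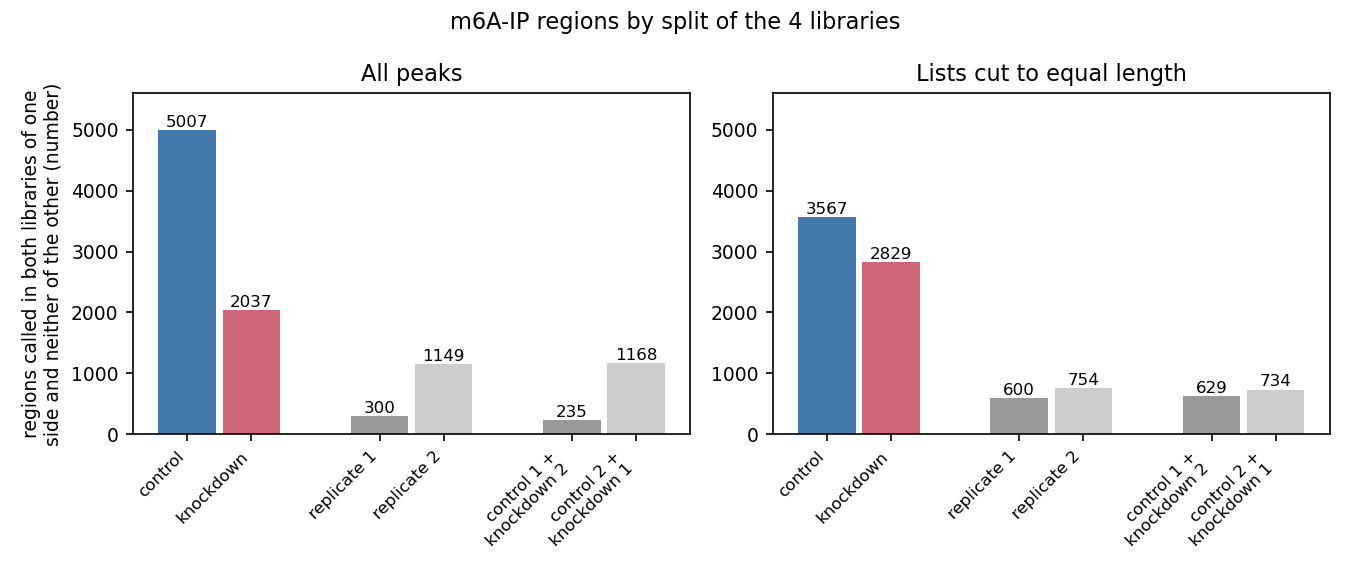
Number of m6A regions (vertical axis) called in both libraries of one side and neither of the other, for each split of the 4 libraries, from all peaks (left) and from lists of equal length (right); blue is control, red is knockdown and grey bars are the crossed splits. The treatment split gives 5007 and 2037 regions from all peaks, and 3567 and 2829 with equal lengths, above every bar of the crossed splits.

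Regions specific to control lay outside genes more often than regions specific to knockdown or found in all 4 libraries. Regions with other patterns of presence were not classified, and the shares were not compared at equal peak strength. On chromosomes 1 to 22 and X, 621 of 4914 control-specific regions (12.6%, 95% Wilson interval 11.7 to 13.6) were outside annotated genes, against 185 of 1985 knockdown-specific regions (9.32%, interval 8.12 to 10.7) and 1688 of 28689 regions found in all 4 libraries (5.88%, interval 5.62 to 6.16). The odds ratio of control-specific to knockdown-specific regions was 1.41 (Fisher's exact test, Benjamini-Hochberg adjusted p = 9.92e-05 over 6 tests). lncRNA genes held 7.22% of control-specific and 4.38% of knockdown-specific regions (odds ratio 1.70, adjusted p = 1.18e-05 by Fisher's exact test), with 5.51% among the regions found in all 4. Regions are not replicates, so these tests describe the 4 libraries, and they were added to those fixed beforehand. Group-specific regions were mostly weak peaks. Their median rank by q-value within the control lists was at percentile 23 and 29.0, against 63.3 and 68.3 for regions found in all 4, and the knockdown-specific regions stood at percentile 31.6 and 31.7 of their lists. Of the 4200 control-specific regions inside a protein-coding or lncRNA gene, 3615 (86.1%) lay in a gene that had other peaks in both knockdown libraries. For knockdown-specific regions this was 1506 of 1770 (85.1%).

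Among the strongest control-specific regions was one in LONP1, a mitochondrial protease gene, on the minus strand of chromosome 19 from 5700851 to 5701055 (hg38), where the deposited folds were 8.67 and 7.59. Another lay in CDC34, encoding a ubiquitin-conjugating enzyme, at chromosome 19 from 536904 to 537105 on the plus strand, with folds of 11.4 and 11. Further ones were in RAB11FIP3 (chromosome 16, 510540 to 510747), JADE2 (chromosome 5, 134559745 to 134559921), KCNIP1 (chromosome 5, 170488825 to 170489743) and the uncharacterised LOC105369958 (chromosome 12, 105506598 to 105507015). Knockdown-specific regions of the highest rank lay in CD2AP, an adaptor of the actin cytoskeleton (chromosome 6, 47503193 to 47503371, folds 7.15 and 9.38), in MYO5B, a myosin motor gene (chromosome 18, 49849626 to 49849791, folds 9.59 and 10.8), and in PSMA4, a proteasome subunit gene (chromosome 15, 78548705 to 78549161, folds 7.82 and 5.07). The others were in ZRANB2 (chromosome 1, 71072188 to 71072684), the calmodulin gene CALM2 (chromosome 2, 47161802 to 47161982) and the helicase gene DDX23 (chromosome 12, 48837323 to 48837779). Folds are the values of the authors' peak caller within each list and were not compared between lists. Whether these regions are exonic or intronic was not analysed here.

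Peaks were assigned to genes without regard to strand. They were called in both control libraries and neither knockdown library for 417 genes. The lncRNA gene LINC02641 led this group with 6 and 7 control peaks, followed by LOC124900762, TRPS1 and MSH4 with 5 and 5 each. TRPS1 encodes a GATA-type transcriptional repressor and MSH4 a meiotic recombination protein. BBS9, a component of the BBSome of cilia, had 4 and 4 peaks, PRKCQ, encoding a protein kinase C, had 3 and 5, and LINC00973 had 5 and 3. KCTD19 and RASSF2 had 3 and 3, and NCMAP, FBXL13 and the docking protein gene GAB2 had 3 and 4. In GAB2, 85.7% of peaks lay where another gene of equal priority overlaps, and in FBXL13 42.9% did, so those assignments are uncertain. Peaks were called in both knockdown libraries and neither control library for 206 genes. MEOX1, a homeobox gene, had 5 and 4, IGFL2 had 3 and 5, and NUP93, a nuclear pore gene, had 4 and 3. The lncRNA genes LOC124901056 and LINC02257 had 4 and 4 and 4 and 3. LOC124902474 had 3 and 4, STYXL2 had 3 and 3, ZFR, an RNA-binding zinc finger gene, had 2 and 3, and the acute-phase gene SAA1 had 2 and 2. SLCO1B3, a hepatic transporter gene, had 3 and 3, the readthrough gene SLCO1B3-SLCO1B7 had 5 and 5 and AARSD1 had 3 and 3, in each case with 100% of the peaks shared with an overlapping gene. The crossed splits gave 99 and 106 genes in all. With equal list lengths the counts were 302 and 296, so the control side exceeded the knockdown side 1.02 times in place of 2.02 times. Without control replicate 2 they were 486 and 432.

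More peaks were called in both control libraries than in either knockdown library for 2137 genes, and the opposite held for 1053 genes, against totals of 962 and 1012 genes in the crossed splits. TNC, encoding the matrix protein tenascin-C, had 22 and 28 control peaks and 8 and 7 knockdown peaks. The receptor phosphatase gene PTPRF had 20 and 20 against 10 and 10, the transcription factor gene GLIS3 18 and 21 against 8 and 8, and KCNIP1, a potassium channel-interacting protein gene, 12 and 13 against 2 and 2. TNRC18 had 34 and 39 against 23 and 23, PRELID2 26 and 26 against 12 and 15, SLC38A4-AS1 28 and 28 against 19 and 19, and NAALADL2 15 and 17 against 6 and 5. In the other direction, BDNF, a neurotrophin gene, had 2 and 2 control peaks and 10 and 9 knockdown peaks. ASPH, an aspartate hydroxylase gene, had 15 and 21 against 27 and 27, and HADHA, a gene of mitochondrial fatty acid oxidation, 0 and 1 against 6 and 6. FNIP1 had 10 and 11 against 17 and 16, and BAZ2B 13 and 13 against 17 and 18. These genes, taken with SLCO1B3-SLCO1B7 from the 8 with the widest gaps in each direction, were chosen after their values were seen. At regions called in all 4 libraries, the recovered local background differed between knockdown and control by -2.29 on the log2 scale in TNC (5 regions), -1.05 in GLIS3, -0.85 in SLC38A4-AS1, -0.40 in PRELID2 and 1.06 in BDNF (1 region each). It differed by 0.09 in TNRC18, -0.06 in FNIP1 and, against the direction of their peak numbers, by -0.39 in both ASPH and BAZ2B. With equal list lengths the counts were 1535 genes with more control peaks and 1589 with more knockdown peaks, so the direction of the imbalance turned. Without control replicate 2 they were 2620 and 2306. Over the 4 libraries, the most peaks were assigned to the overlapping protocadherin genes PCDHGA1, PCDHGA2, PCDHGA3 and PCDHGB1, which share the same 46, 50, 42 and 40 peaks, then PCDHGA4 (39, 45, 37 and 35) and RANBP2 (40, 42, 35 and 34), where 74.8% of peaks were shared with another gene, so that its rank is uncertain.

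**Figure D2:**
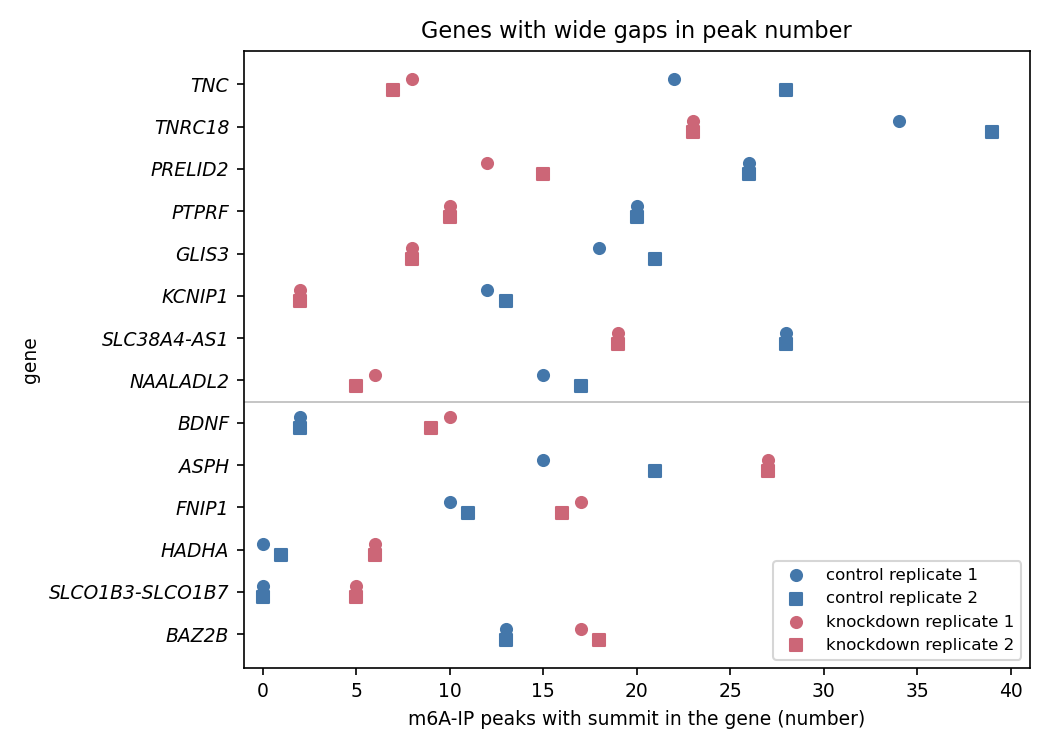
Number of m6A peaks with their summit in each gene (horizontal axis) in control (blue) and knockdown (red) libraries, replicate 1 as circles and replicate 2 as squares, for genes taken from the 8 with the widest excess in each direction, those with more control peaks above the line. TNC lies at 22 and 28 in control and 8 and 7 in knockdown, and BDNF at 2 and 2 against 10 and 9.

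Genes of most lists, chromatin and transcription regulators among them, carried m6A peaks more often than other genes. All 22 chromatin remodeller genes had peaks in both control libraries, as did 27 of 29 genes of RNA polymerase II transcription and elongation, 25 of 28 histone-modifying enzyme genes and 22 of 23 DNA repair genes, against 29.8% of other protein-coding and lncRNA genes. Of 477 ZNF genes, 353 (74.0%) had peaks in both, against 29.3% of other genes (Fisher's exact test, adjusted p = 1.27e-87). The remaining lists above other genes were the m6A machinery, heterochromatin and DNA methylation, and PI3K, AKT and mTOR signalling with 19 of 21 each, nuclear exosome with 17 of 19, splicing factors with 21 of 25, immediate-early factors with 19 of 23, Wnt and TGF-beta signalling with 24 of 28, cell cycle with 20 of 24, epithelial junction genes with 21 of 24, nuclear and long noncoding RNAs with 14 of 20, and endometrial and hormone response genes with 13 of 24. In all, 17 of 21 lists differed from other genes by Fisher's exact test with Benjamini-Hochberg adjustment, 16 above and 1 below. Blood, immune and endothelial markers were below, with 1 of 19 genes (5.26%, adjusted p = 0.0258 by Fisher's exact test), PECAM1. Stromal and fibroblast markers (4 of 16), ribosomal protein genes (22 of 83), replication-dependent histone genes (19 of 69) and mitochondrially encoded genes (3 of 13) did not differ past the threshold. Against random lists matched on gene length, a permutation test, the histone genes stood above, with 19 genes against a matched median of 7 (adjusted p = 0.00028) and the endometrial list did not (adjusted p = 0.0847). Expression is not known from peak lists, so a gene without peaks may not have been transcribed. Of the 38164 protein-coding and lncRNA genes, 18177 were lncRNA genes, and 25402 genes had no peak in any library. These shares therefore do not separate methylation from transcription.

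None of the 21 lists held a share of genes with more control peaks that differed from other genes by Fisher's exact test after adjustment, and 3 lists did at an unadjusted p under 0.05, each below other genes. These were ZNF genes (48 of 353, 13.6% against 18.9%, unadjusted p = 0.0104 by Fisher's exact test, adjusted p = 0.217), immediate-early factors (0 of 19) and replication-dependent histone genes (0 of 19, unadjusted p = 0.0352 each, adjusted p = 0.246). Without control replicate 1 or without knockdown replicate 1, the ZNF and histone lists passed, and without knockdown replicate 2 the ZNF list did. Among transcription elongation genes, 8 of 27 had more control peaks (29.6% against 18.7%, adjusted p = 0.604 by Fisher's exact test), including the bromodomain gene BRD3 (14 and 14 against 12 and 10), CDK9, the kinase of P-TEFb (5 and 7 against 4 and 3), and NELFA of the pausing factor NELF (6 and 6 against 2 and 4). In PI3K and AKT signalling 4 of 19 did, with AKT1 at 6 and 11 against 3 and 3 and RICTOR at 5 and 4 against 3 and 3. Among chromatin genes, EP400 had 18 and 22 against 13 and 13, KMT2B 19 and 20 against 14 and 16, UHRF1 15 and 16 against 10 and 10, and SMARCA4 12 and 15 against 11 and 9. In DNA repair, ATM had 7 and 11 against 3 and 3. PAX8, a transcription factor of the Müllerian tract, had 18 and 20 against 14 and 13. The endometrial list held 52 peaks ± 2.83 (SD, n = 2) in control and 41.5 ± 4.95 (SD, n = 2) in knockdown, a ratio of 0.798 against 0.912 over all protein-coding and lncRNA genes. Its own test found 2 of 13 genes with more control peaks (15.4% against 18.8%, adjusted p = 1 by Fisher's exact test), and 2 of 13 had more knockdown peaks.

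Genes with more knockdown peaks were over-represented among ribosomal protein and splicing factor genes. Of 33 ribosomal protein genes with peaks in both knockdown libraries, 12 had more peaks than in control (36.4% against 9.48% of other genes, adjusted p = 0.000607 by Fisher's exact test over 21 lists). Over the whole list, 40 and 62 control peaks compared with 83 and 75 knockdown peaks, or 51 ± 15.6 against 79 ± 5.66 (SD, n = 2 each). Examples were RPL14 (2 and 2 against 4 and 5), RPL19 (1 and 2 against 4 and 3) and RPS9 (0 and 1 against 3 and 3), while RPL36 had 2 and 2 against 1 and 1. Ribosomal protein genes have many near-identical pseudogenes, so their peaks are uncertain. The call held with equal list lengths, without each library in turn and against random lists matched on the number of peaks (permutation test, adjusted p = 0.0042). The share itself rose to 57.6% (19 of 33, other genes 20.8%) without control replicate 2 and to 61.4% (27 of 44, other genes 17.2%) without knockdown replicate 2. Of 22 splicing factor genes, 7 had more knockdown peaks (31.8% against 9.51%, adjusted p = 0.0353 by Fisher's exact test), with 84 and 99 control peaks against 108 and 108. They included RBM25 (6 and 7 against 10 and 10), SRSF11 (5 and 5 against 8 and 6), HNRNPDL (1 and 1 against 3 and 4) and SRSF7 (0 and 0 against 2 and 2), whereas SRRM2 had 15 and 17 against 13 and 13. The splicing factor call was lost against matched random lists (permutation test, adjusted p = 0.189) and, by Fisher's exact test, without control replicate 1 (adjusted p = 0.143) and with summits in exactly 1 gene (adjusted p = 0.154). The list test in this direction was not among those fixed beforehand and was added after the values were seen. Without control replicate 2, epithelial junction genes also passed (12 of 22) and ZNF genes passed below other genes (48 of 351).

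**Figure D3:**
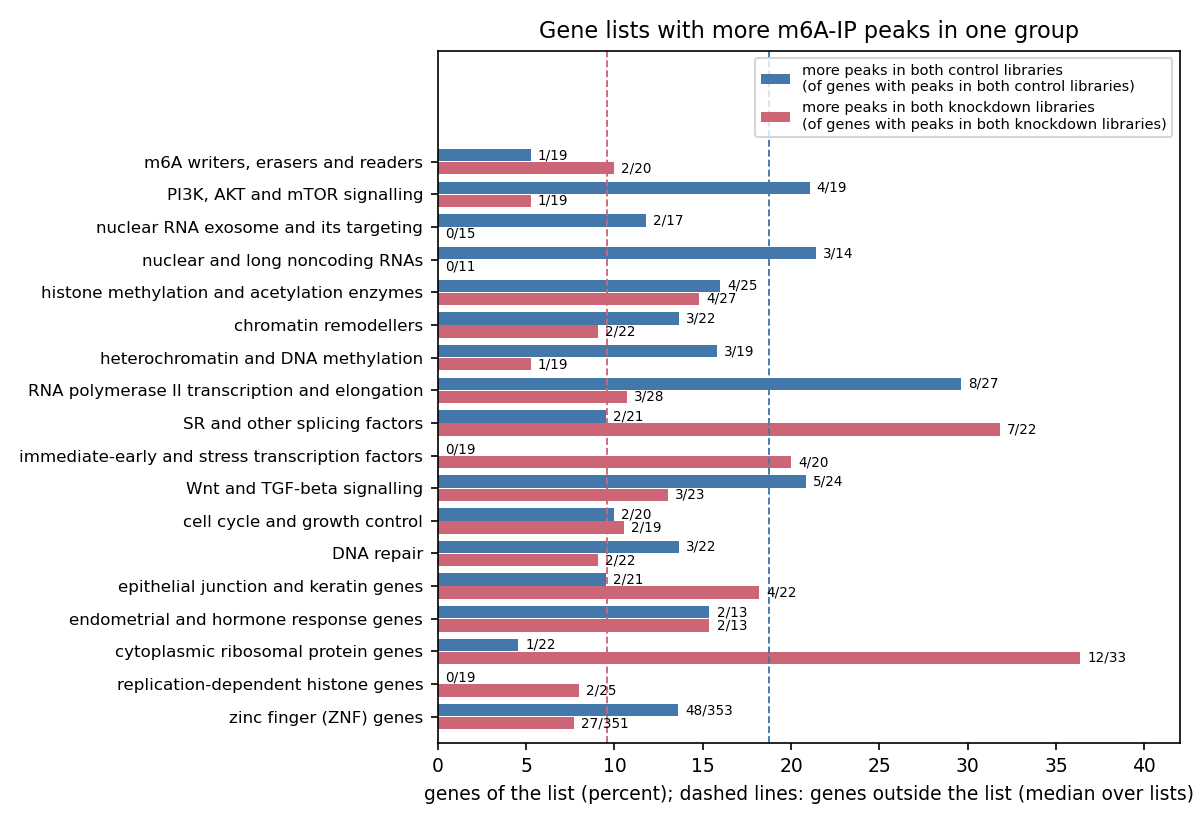
Percent of genes in each list (horizontal axis) with more m6A peaks in both control libraries (blue, of genes with peaks in both) or in both knockdown libraries (red, of genes with peaks in both), with the number of genes beside each bar and the percent among other genes as dashed lines; lists with fewer than 10 such genes are not drawn. Ribosomal protein genes (12 of 33) and splicing factors (7 of 22) stand furthest above the red line.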

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

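The tests of deeper calling, of weak peaks, of one-sided genes and of list length were chosen only after the result was seen. The abundance test had its bounds set beforehand, but its restriction to genes with shared regions was made after its value was known. A further pattern, low fold at abundant RNAs, had also been examined and was set aside in favour of the ribosomal protein genes once both results were known; its values stand under the other observations.

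Peaks on the spike-in sequences, which no comparison used, were called in every library, 5 in control replicate 1, 4 in control replicate 2, 4 in knockdown replicate 1 and 3 in knockdown replicate 2. No spike-in peaks on a sample without antibody were analysed here to set beside them.

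More regions were specific to control (5007) than to knockdown (2037). Deeper calling in control replicate 2 may account for part of this. Control replicate 1, set against each knockdown library alone, had 1.10 and 1.20 times as many unshared regions as they had, a mean of 1.15, whereas control replicate 2 had 4.73 times as many as control replicate 1. The bound for this test was set with the values in view. An excess of 1.26 times remained with equal list lengths. Without control replicate 2 it was 1.55 times (6581 against 4237 regions), where control-specific regions need 1 library and knockdown-specific ones 2. The crossed splits, which mix the groups, were uneven too, with more regions on the side holding control replicate 2. They gave 300 against 1149 and 235 against 1168 regions from all peaks. With equal list lengths they gave 600 against 754 and 629 against 734. The remaining 1.26 times is thus not particular to the treatment split. Loss of methylation after knockdown stays open and was not tested apart from depth.

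More regions followed the treatment (7044) than either crossed split, of which the highest gave 1449, so 1 of the 3 possible splits gave as many, and 3 splits are too few for a share under 0.05. Changed RNA abundance in genes with shared regions cannot be told apart. It was tested at shared regions whose background lay above the floor, by 0.5 on the log2 scale. There the median log2 change of local background was 0.02 in genes with more control peaks and 0.10 in those with more knockdown peaks. Over all shared regions these medians were -0.0007 and 0.02, against 0.003 in other genes. Above the floor, the differences from other genes were -0.03 (95% bootstrap interval -0.07 to -0.01) and 0.05 (0.01 to 0.08). They were small but lay on the side that changed abundance predicts. The medians are over genes, which are not replicates, so the intervals describe these libraries. Single genes lay far out on that side (TNC -2.29, GLIS3 -1.05, BDNF 1.06), GLIS3 and BDNF from 1 region each. ASPH and BAZ2B, with more knockdown peaks, lay on the opposite side (-0.39 each). In control replicate 2 and knockdown replicate 1 alone, where the background was recovered most closely, the differences were -0.04 (-0.07 to -0.01) and 0.02 (-0.02 to 0.06), the latter with 0 inside its interval. The bound of 0.1 set beforehand was met but was too loose to exclude it, since the genes went both ways (quartiles -0.28 and 0.25), and for the 623 genes with peaks on one side only it stays open too, as just 3 genes with peaks on one side only held a region called in all 4 libraries. Weak peaks near the threshold (10.1% of control-specific regions above the median q of both lists) cannot be told apart from a local change of methylation either. That value lay just above the bound under which weak peaks would have been taken as the cause. The bound was set with the value in view, so it decides nothing. Changes of whole transcripts cannot be told apart either. Of region pairs within a gene, 83% had the same direction, against 54.9% to 61.5% in 1000 shuffles. This lay above the shuffles but below the bound set beforehand for whole transcripts.

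Ribosomal protein genes had more knockdown peaks more often than other genes. The length of the control replicate 2 list is argued against as the cause, as the higher adjusted p with equal list lengths and without that library was 0.00039. Reads shared with ribosomal protein pseudogenes are argued against only where they would raise peaks in genes and pseudogenes alike. The pseudogenes held 65 and 73 control peaks and 57 and 66 knockdown peaks, a ratio of 0.891 against 1.55 in the genes. Pseudogene reads placed on the genes alone stay open, since they would add no peaks to the pseudogenes. Changed abundance of their RNA cannot be told apart, again at shared regions above the floor. The median log2 background change was 0.03 over 18 genes, with a 95% bootstrap interval of the difference from other genes of -0.20 to 0.07. An effect of the knockdown on these transcripts remains a hypothesis, found and tested on the same 4 libraries.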

How the results depend on the processing

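Of 113 alternatives, 89 kept the result by its own criterion (the same direction and side of the threshold for values with a test, a shift under 1 SD for the share of control regions in knockdown, and within 1.5 times for counts), 21 moved it and 3 ended a call, and 60 left out a library; those with strand ignored, with peaks under a stronger opposite-strand peak removed, and for lists with more knockdown peaks were chosen after seeing the data. Counts were scored for each side alone, so an alternative could count as kept while the sides drew level. With equal list lengths, the ratio of control to knockdown side went from 2.02 to 1.02 for genes with peaks in a single group. For group-specific regions it went from 2.46 to 1.26, and the counts behind both ratios were scored as kept. Genes with more knockdown peaks then numbered 1589 in place of 1053, which was scored as moved. An overlap of at least 50% of peak and region put the share of control regions in knockdown at 67.3%. The causes were not tested. The difference in the share outside genes kept its sign but went from -0.823 to -0.473 points with equal list lengths, and its permutation test cannot pass 0.05 in this design, nor can those of peak number and covered length. Lists with more knockdown peaks fell from 2 to 1 against matched random lists. Leaving out each library gave 6581 to 11330 control-specific and 2522 to 4549 knockdown-specific regions, 486 to 786 and 245 to 432 genes with peaks on one side, 2620 to 4421 genes with more control and 1358 to 2306 with more knockdown peaks, where 1 library in place of 2 makes each condition easier to meet. The highest control-side values came without control replicate 1, the highest knockdown-side gene values without control replicate 2, and the highest number of knockdown-specific regions without knockdown replicate 2. Lists with more control peaks ranged from 0 to 2 and lists with more knockdown peaks from 1 to 4. The splicing factor call was lost without control replicate 1, with summits in exactly 1 gene (adjusted p = 0.154) and against matched random lists, its adjusted p ranging from 0.0011 to 0.189. Not run were exonic summits alone and the m6A motif with its 100 base window. Depth limits every count, since control replicate 2 was called on a background 1.56 times that of control replicate 1.

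The replicate block, as the within-number ratio of knockdown to control peaks, gave 0.906 (exact sign-flip p = 0.5, the smallest that 2 pairs allow), against 0.903 without it. Same-numbered libraries of different groups shared 65.3% of regions and differently numbered ones 65.2%. The overlap thus gave no sign of pairing by number, but 2 pairs of each kind are too few to exclude it.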

Other observations

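Peak numbers of related chromatin regulators differed in both directions. CHD9 had 16 and 18 control peaks and 23 and 21 knockdown peaks, and CHD2 10 and 16 against 19 and 21, while ATRX had 12 and 12 against 8 and 11. The DNA methyltransferase genes also parted, with DNMT1 at 3 and 7 against 9 and 11 and DNMT3A at 5 and 4 against 3 and 2. The Wnt co-receptor genes LRP5 (16 and 18 against 14 and 15) and LRP6 (15 and 18 against 12 and 12) had more control peaks, and SMAD3, an effector of TGF-beta signalling, had 11 and 12 against 14 and 13. Among DNA repair genes RAD50 had 9 and 11 against 13 and 17. These genes were named after their values were seen and no test was made of single genes.

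Group-specific regions gathered in genes of a single direction. Of 423 genes with at least 3 such regions, 248 held control-specific ones alone, 50 knockdown-specific ones alone and 125 both.

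Peaks on abundant nuclear RNAs had low folds on the strand of the gene. In MALAT1, control replicate 1 had 0 plus-strand peaks and 1 opposite-strand peak at a fold of 3.92. In the other libraries the median plus-strand fold was 1.19 in control replicate 2, 1.45 in knockdown replicate 1 and 1.26 in knockdown replicate 2, at median backgrounds of 604, 432 and 542 reads, and the opposite-strand peaks had median folds of 3.0, 6.14 and 3.78. In NEAT1 the plus-strand medians were 1.43, 1.69, 2.34 and 1.86 and the opposite-strand medians 3.97, 3.76, 5.78 and 4.68. Within each list the median fold was 5.39, 5.61, 5.26 and 5.19 in decile 5 of local background and 2.55, 2.52, 2.79 and 2.59 in decile 10. Peaks of ribosomal protein genes had median folds of 2.94, 2.95, 2.85 and 2.89. Recovered pileups ended at 750 reads in control replicate 2 and knockdown replicate 1, where 15 peaks stood at that value and 0 above it. Folds were read within each list and not compared between lists.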
